A study of Rattus norvegicus with 6 samples.

How the data were processed

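RNA of the striatum was measured in 6 samples, 3 from control rats and 3 from rats given MnCl2. Per the labels' protocols, RNA was extracted with RNeasy Plus Mini columns and libraries were made with the NEBNext Ultra RNA kit after poly(A) selection. The deposited counts are whole numbers of reads per Ensembl gene, not normalised, with 1 column per sample. The submitters' processing notes name bcl2fastq 2.17, STAR 2.5.2b, DESeq2 with no version, and the build Rnor_6.0 (rn6). The counting tool, the annotation release, and the handling of strand and of reads with several matches are not given in the sources used here. Per the file headers, each gene also has its exon positions, strand and summed exonic length. A table of the whole series held the same counts as the files of single samples, with 0 cells that differed, so it was not run as an alternative. Poly(A) selection favours polyadenylated transcripts, so short mtDNA features are measured only as far as their reads carry over from longer transcripts or escape selection, and the share of mtDNA counts is a share of selected RNA.

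Groups and sample numbers were taken from the labels. All 32552 gene IDs were looked up in a table of rat RefSeq genes on GRCr8, and 0 matched, since the table gave no Ensembl IDs. The files do not pair the IDs with names. The 53 gene lists fixed before the data were examined, among them the mitochondrial fusion and fission genes, the markers of striatal cell types and the lists without shared genes, were therefore not analysed here, with the exception of the mtDNA-encoded genes, which were taken by position as the 13 features of over 200 bases on the mitochondrial chromosome. The other 22 mtDNA features are 60 to 75 bases long, the size of transfer RNA genes. The rule for named genes, also fixed beforehand, took genes with a symbol by adjusted p and a set of mitochondrial genes by symbol. Without symbols it could not be applied, and the 2 genes with the smallest edgeR p in each direction are given by ID. Coordinates are 1-based on Rnor_6.0.

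Counts were filtered with filterByExpr, which kept 15252 genes, scaled with TMM and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test with robust estimation, no block), with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 22.8%. Gene sets were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated one, and with fry. Shares of counts were compared with two-sided exact permutation tests, and the interval of a share in 1 library is a 95% exact Clopper-Pearson interval that covers counting error only. Components were computed from log2 CPM of the 1000 most variable genes. Alternatives fixed beforehand were DESeq2 size factors or library size alone in edgeR, no filter or a mean CPM of at least 1, DESeq2 1.42.0, limma-voom with and without sample weights, the ID number as a block, 1 surrogate variable (sva 3.50.0), a threshold of 0.1, a minimum fold of 1.5, and each replicate left out in turn. DESeq2 gave a p for 22856 genes and no adjusted p for 5200 of these.

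The labels number the IDs from 1 to 3 in both groups, which put control 1 with Mn-exposed 13, control 2 with Mn-exposed 14 and control 4 with Mn-exposed 17. Deviations from the group means correlated, over genes, at 0.417, 0.109 and 0.227 in these pairs. Every pair was above 0.1, the minimum set for treating numbers as pairs, and the numbers were used as a block on that basis. The block thus rests on correlations in the same data that it is fitted to. Higher gene counts with it are in part built in and are no independent support. The labels state no shared litter, day or batch, the second pair is only just above the minimum, and 2 of the 3 Mn-exposed samples correlated better with another control: Mn-exposed 14 with control 4 (0.145) and Mn-exposed 17 with control 2 (0.274).

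The steps were tested on simulated counts of the 15252 genes with the means, spread and library sizes of the Mn-exposed and control samples. Each gene was drawn independently in each library, so variation shared between genes was not simulated. With 200 genes changed 2-fold, edgeR recovered 25.5% with 3 false calls, DESeq2 58% with 25 false calls and limma-voom 12.5%. At 4-fold the shares were 89%, 93% and 87%, with 20 false among 198 calls, 56 among 242 and 19 among 193. In 20 simulated sets with no change, DESeq2 called 10 to 41 genes (median 21.5) and edgeR 0 to 1.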

Results

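Poly(A)-selected RNA of the striatum, the input nucleus of the basal ganglia, was sequenced from male Sprague-Dawley rats. Manganese (Mn) is an essential metal that is toxic to the brain in excess and accumulates in the basal ganglia. There were 3 control samples from rats given 0.9% NaCl into the peritoneal cavity and 3 samples from rats given MnCl2 at 25 mg/kg over 15 days. The samples are named here by the numbers in their labels: control 1, 2 and 4, and Mn-exposed 13, 14 and 17. The labels give each sample its own ID without stating that each came from a different rat, so p-values measure the spread between these samples. Reads had been counted over 32552 annotated genes of the Rnor_6.0 build. Total counts were 21987831, 32569760 and 25188140 in control 1, 2 and 4, and 21754379, 25089300 and 27882443 in Mn-exposed 13, 14 and 17. The totals of the 2 groups overlapped (two-sided exact permutation p = 0.6, n = 3 each). Between 19356 and 20094 genes had at least 1 count in a sample. As a check for a library entered more than once, the chi-square per degree of freedom over genes, which covers counting error only, ran from 15.82 to 176.6 over the pairs of libraries, and all 6 were kept.

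The comparison of Mn-exposed with control striatum asks how exposure alters the transcript profile, in a study whose title concerns mitochondrial dynamics. The files identify genes by Ensembl ID and position and do not pair the IDs with names, so single genes are given here by ID, and the 2 with the smallest p in each direction are described. Of the 2 higher in Mn-exposed samples, the larger fold was that of ENSRNOG00000001514, on the plus strand of chromosome 3 from 59153280 to 59163913, with 9 exons after merging and 2330 exonic bases. It stood at 2.18 ± 0.356 CPM (counts relative to library size, with TMM scaling) in controls and 11.7 ± 3.6 in Mn-exposed samples (SD, n = 3 each), a fitted log2 fold change of 2.43 with a standard error of 0.27. ENSRNOG00000018399, on the plus strand of chromosome 15 from 34187223 to 34194118 with 17 merged exons, stood at 27.2 ± 2.61 CPM in controls and 61.6 ± 7.74 in Mn-exposed samples, a 2.27-fold difference (log2 fold change 1.18, SE 0.14). In the other direction, ENSRNOG00000016299, on the minus strand of chromosome 5 from 72283313 to 72287669 with 5 merged exons, stood at 20.3 ± 6.06 CPM in controls and 6.08 ± 0.592 in Mn-exposed samples (log2 fold change -1.74, SE 0.23). ENSRNOG00000011541, on the minus strand of chromosome 10 from 105618326 to 105628091 with 4 merged exons, stood at 75.3 ± 4.6 CPM in controls and 39.4 ± 6.22 in Mn-exposed samples (log2 fold change -0.94, SE 0.14). In each of these 4 genes all 3 Mn-exposed samples lay beyond all 3 controls, which their selection by p makes nearly certain. On the chromosome, 0 of the 4 overlapped another annotated gene. None passed the main test: the adjusted p of edgeR's quasi-likelihood test was 0.35 for ENSRNOG00000001514 and ENSRNOG00000018399, 0.367 for ENSRNOG00000016299 and 0.505 for ENSRNOG00000011541. DESeq2 gave the same 4 genes adjusted p values of 1.43e-11, 4.06e-08, 7.89e-08 and 3.94e-05 in that order.

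**Figure D1:**
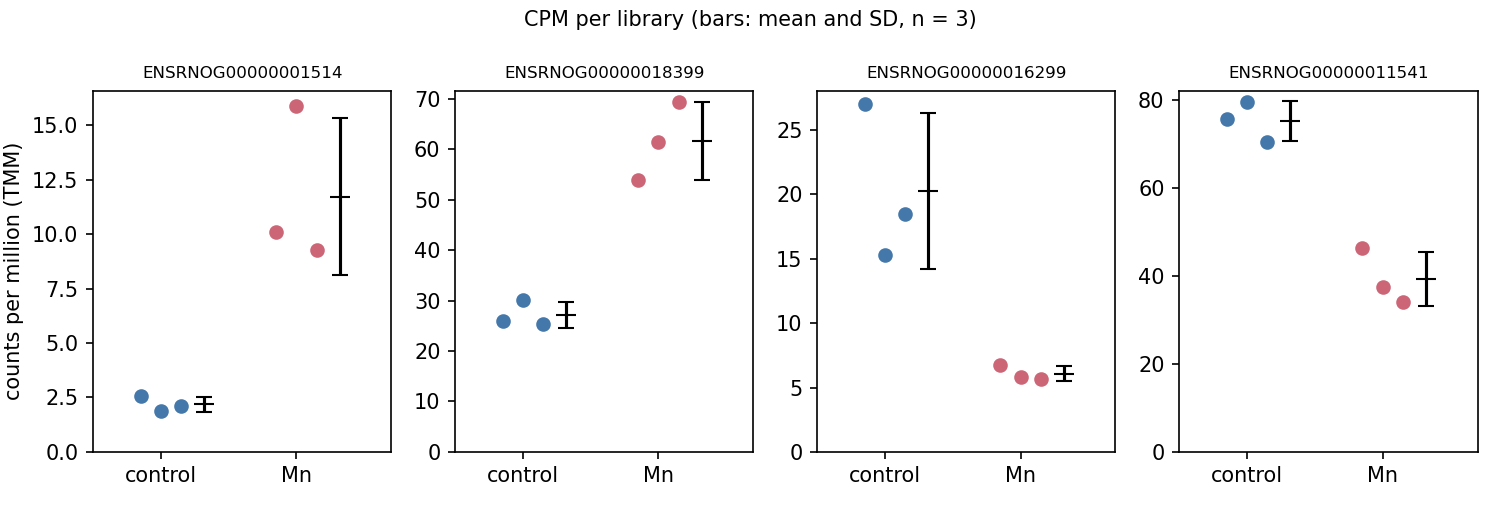
CPM, with TMM scaling, of the 2 genes with the smallest p in each direction, one panel per gene, with a linear axis from 0. Points are the 3 control and 3 Mn-exposed samples, and black bars are the mean and SD. The groups do not overlap in any of the 4 panels, which selection by p makes nearly certain.

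Among the 15252 genes tested, 0 passed an adjusted p of 0.05 with edgeR's quasi-likelihood test (smallest adjusted p = 0.35), and 1139 had an unadjusted p under 0.05, where 763 would be expected by chance on average. Other divisions of the 6 libraries, 3 against 3, gave 73 to 2058 such genes, so 1139 lies within that range. Of these 1139 genes 650 were higher and 489 lower in Mn-exposed samples. Scaling by library size alone, in place of TMM, moved the median log2 fold change of all genes from 0.02 to 0.12 and the division to 1239 higher and 244 lower. DESeq2, run on 22856 genes with a count, called 86 genes, 49 higher and 37 lower in Mn-exposed samples, and limma-voom called 0. All 86 had groups that did not overlap in CPM, which selection by p in these samples makes likely. Among them 58 had a fold of at least 2, and the median absolute log2 fold change of the 86 was 1.28. Of the 86 genes, 85 entered the edgeR test, and these 85 had the same sign and an unadjusted p under 0.05 there. Over all genes tested, 2507 (16.4%) had groups that did not overlap, where chance gives 10% on average for 3 against 3. With the ID number as a block, edgeR's count at an unadjusted p under 0.05 was 2115, while its adjusted count stayed at 0. DESeq2's count of calls with the block was 276, of which 68 were among the 86. That block was accepted from correlations in these same data, so part of these rises is built in. The DESeq2 count was 295 without control 1, 38 without control 2, 29 without control 4, 751 without Mn-exposed 13 and 24 without Mn-exposed 17, and the edgeR unadjusted count was 678 without control 4, 2351 without Mn-exposed 13 and 576 without Mn-exposed 17. All 86 kept their sign in each of the 6 fits with 1 library left out, which groups that do not overlap make nearly certain in advance. Of the 86, 15 were called in every one of these fits.

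Transcripts of the mitochondrial genome made up a smaller part of the counts in every Mn-exposed sample than in any control. The 35 annotated mitochondrial DNA (mtDNA) features took 16.59%, 13.95% and 13.9% of counts in control 1, 2 and 4, and 13.76%, 8.639% and 12.41% in Mn-exposed 13, 14 and 17. The mean share was 14.8% ± 1.54 in controls and 11.6% ± 2.65 in Mn-exposed samples (SD, n = 3 each), a difference of -3.21 percentage points. The two-sided exact permutation p was 0.1, the smallest this test can give for 3 samples against 3, so the test could not pass 0.05. Without Mn-exposed 14 the difference was -1.73 points, with a two-sided exact permutation p of 0.4. Without control 1 it was -2.32 points, with a two-sided exact permutation p of 0.2. At these depths counting error is small: the 95% exact binomial interval (Clopper-Pearson) of the share in Mn-exposed 14 ran from 8.6276% to 8.6496%.

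**Figure D2:**
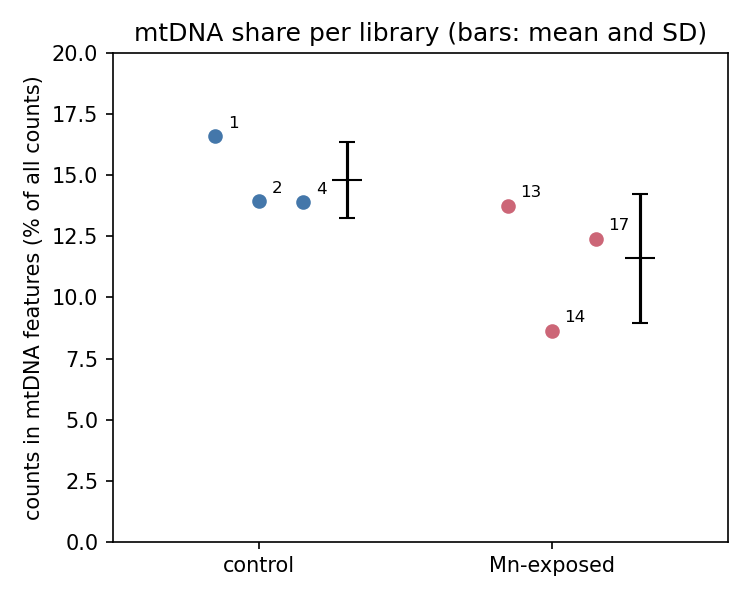
Share of all counts in mtDNA features, in percent, for each library, numbered as in the labels, with black bars for the mean and SD of each group. The 3 Mn-exposed libraries lie between 8.639% and 13.76% and the 3 controls between 13.9% and 16.59%.

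The mtDNA list was the only gene list that could be formed by position. Its 13 longer features, of 204 to 1830 bases, had a median log2 fold change of -0.40, and all 13 were negative, from -0.54 to -0.37. The largest share of counts came from the feature at positions 5323 to 6867 on the plus strand of the mitochondrial chromosome, at 41150 CPM in controls and 28910 in Mn-exposed samples, with a log2 fold change of -0.51 (SE 0.25). The feature with the most negative estimate, at 7006 to 7689, stood at 12430 CPM in controls and 8571 in Mn-exposed samples (log2 fold change -0.54, SE 0.23). At the other end, the minus-strand feature at 13543 to 14061 stood at 2779 CPM in controls and 2155 in Mn-exposed samples (log2 fold change -0.37, SE 0.22). It shares bases with the plus-strand feature at 11736 to 13565, and reads of the 2 strands cannot be told apart with a library kit that does not mark strand. Among the 13 features, 0 passed edgeR's test over all genes and 0 adjusted over the list alone, with adjusted p over the list between 0.179 and 0.261, and DESeq2 called 0. As a set they were lower relative to other genes with camera's preset correlation of 0.01 (p = 1.03e-07). This call was lost with the correlation estimated from the data, 0.894 (camera p = 0.175), and fry gave p = 0.118. The fry test is self-contained: it asks whether the features move one way on balance and does not compare them with other genes. With the ID number as a block and an estimated correlation, camera gave p = 0.252. Without Mn-exposed 14 the median log2 fold change was -0.22 and without Mn-exposed 13 it was -0.59.

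**Figure D3:**
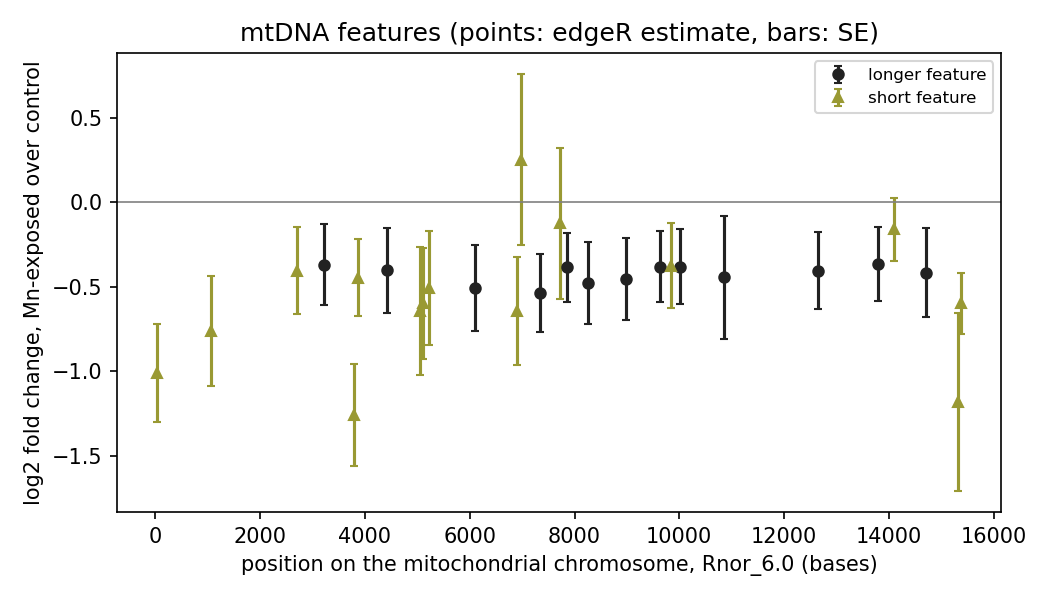
Log2 fold change of the 28 tested mtDNA features, Mn-exposed over control, against their midpoint on the mitochondrial chromosome (Rnor_6.0, bases), with bars for the standard error. The 13 longer features (circles) lie between -0.54 and -0.37, and the 15 short ones (triangles) between -1.26 and 0.25.

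The libraries did not separate cleanly by treatment. The first component of the 1000 most variable genes held 44.7% of the variance and set Mn-exposed 14 (34.1) and 17 (20.4) against control 1 (-24) and Mn-exposed 13 (-22.5), with control 2 (-6.34) and 4 (-1.59) between them. Correlations of log2 CPM averaged 0.9751 over the 6 pairs within a group (0.9634 to 0.9892) and 0.9714 over the 9 pairs between groups (0.9564 to 0.9825). Control 1 correlated best with Mn-exposed 13, at 0.9825. Mn-exposed 13 also correlated better with control 2 (0.9794) and 4 (0.9746) than with Mn-exposed 14 (0.9634) and 17 (0.9718). The mtDNA share moved with the first component, computed without mtDNA features, over the 6 libraries (Pearson r = -0.891, exact permutation p = 0.00694, Benjamini-Hochberg adjusted over 3 relations 0.0167; Spearman rho = -0.829, exact p = 0.0583, adjusted 0.0874). Without the 2 libraries farthest from the median on that component, Mn-exposed 14 and 17, r was -0.568. Leaving out the ends narrows the range, so whether the relation of share and component rests on those libraries cannot be told. A difference between libraries by gene length moved with both: the slope of expression on the length of the gene on the chromosome followed the first component (Pearson r = 0.913, exact permutation p = 0.0111, adjusted 0.0167; Spearman rho = 0.829, exact p = 0.0583, adjusted 0.0874), with r = 0.845 without Mn-exposed 14 and 17. Slope and component were computed from the same expression values, so part of their relation is built in. The mtDNA share followed this slope with r = -0.933 (exact permutation p = 0.0194, adjusted 0.0194) and rho = -0.6 (exact p = 0.242, adjusted 0.242). Without Mn-exposed 14 and control 1, the 2 farthest libraries, r was -0.385, and for the same reason whether that relation rests on them cannot be told. When control 1 and Mn-exposed 13 were both left out, an alternative chosen after this resemblance was seen, edgeR called 58 genes, 41 higher and 17 lower, of which 11 were among the 86 called by DESeq2 over all 6 libraries.

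**Figure D4:**
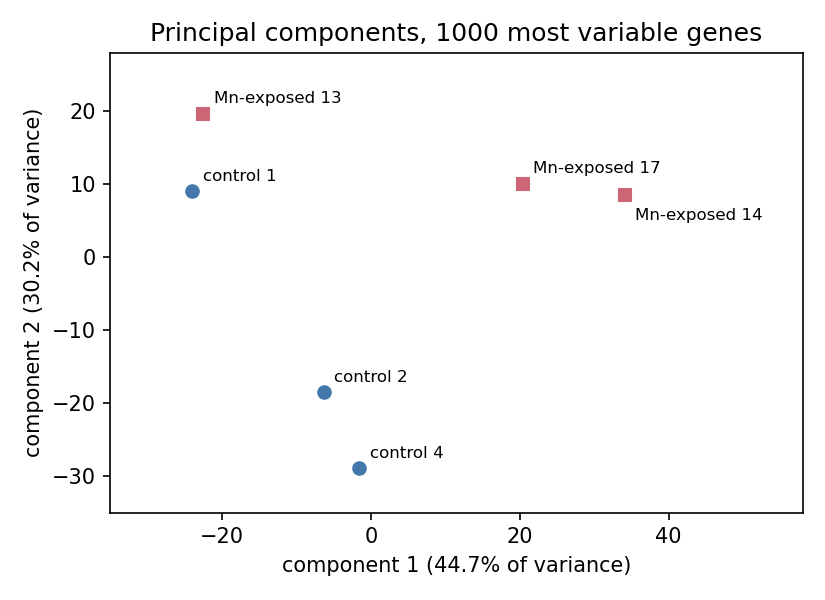
Principal components 1 and 2 of log2 CPM over the 1000 most variable genes, with 44.7% and 30.2% of the variance, for the 3 control (circles) and 3 Mn-exposed (squares) libraries. Control 1 and Mn-exposed 13 lie together at the left, at -24 and -22.5 on component 1.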

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

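The edgeR fits with the newer dispersion estimate, with the gene span trend removed, without mtDNA features, without control 1 and Mn-exposed 13 together, the replicate block with an estimated correlation, and all DESeq2 refits were chosen after the data were seen. Of the alternatives for the count of genes changed by Mn, 19 gave 0 calls, as did edgeR with all 6 libraries, and DESeq2 (86) and the fit without control 1 and Mn-exposed 13 (58) did not. Their smallest adjusted p ran from 1.43e-11 (DESeq2) to 0.996 (without Mn-exposed 17). Genes at an unadjusted p under 0.05 (1139) numbered 2131 with limma-voom sample weights, 2115 with the replicate block, 2692 without control 1 and Mn-exposed 13, and 576 to 2351 when 1 replicate was left out. The DESeq2 count of 86 was 892 without control 1 and Mn-exposed 13, 276 with the replicate block, and 24 to 751 with 1 replicate left out; fewer libraries both raised and lowered it, and the cause was not tested. The median log2 fold change of the 13 longer mtDNA features, -0.40, was not past 0.05 with an estimated correlation (p = 0.175) or fry (p = 0.118), nor with both the replicate block and an estimated correlation (-0.43, p = 0.252). Its sign held under all alternatives, from -0.59 (without Mn-exposed 13) to -0.22 (without Mn-exposed 14), and the mtDNA share difference stayed between -4.29 and -1.73 points. The first component held 42.1% of the variance over all genes, against 44.7%. The block changed no other call. The 4 named genes kept their sign under all alternatives, which was nearly certain in advance since their groups do not overlap. All 4 passed with DESeq2, and 3 without control 1 and Mn-exposed 13. Depth was not the limit for abundant features. With 3 libraries per group, edgeR recovered 25.5% of simulated genes changed 2-fold and 89% of those changed 4-fold. The simulated genes lacked variation shared between genes, so these shares need not hold for the real counts.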

Other observations

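The DESeq2 count, the mtDNA share without Mn-exposed 14 and the set tests with an estimated correlation or fry were fixed before the data were examined. The tests on the short mtDNA features, chromosomes, neighbouring genes, splits, simulated sets, pairs of libraries left out, gene span, labels and correlations between libraries were chosen after the main results were seen. Short mtDNA features, of 60 to 75 bases, had a lower median than the longer ones: 15 were tested, with a median log2 fold change of -0.60, 14 of them negative, 3 at an unadjusted edgeR p under 0.05 and 0 past the adjusted threshold. The set's camera p was 6.87e-07 with the preset correlation and 0.149 with an estimated correlation, and fry gave 0.0998. The difference between short and longer features was not tested. DESeq2 called 1 mtDNA feature, the minus-strand one at 3761 to 3831, singled out after its values were seen, with 4.62 CPM in controls, 1.931 in Mn-exposed samples and an adjusted p of 0.0285. Coverage was uneven among the longer features: the one at 10160 to 11537, of 1378 bases, had 0.584 CPM per base, against 2.57 to 26.8 in the 12 others, and its CPM varied by 34.1% among controls. No explanation for this was tested.

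The 85 DESeq2 calls that edgeR also tested had a median exonic length of 2990 bases, against 2341 in all genes tested, and a median of 11.05 CPM against 19.2. Chromosome 1 held 15 of them where its share of tested genes gives 10.7, and no chromosome passed Fisher's exact test after Benjamini-Hochberg adjustment over 21 chromosomes (smallest adjusted p = 0.657, chromosome 17, 6 calls). There were 4 calls within 100 kb of another call, and a share of 0.23 of 1000 random draws of genes gave as many. The signed z of neighbouring genes that do not overlap, from the edgeR test, correlated at 0.0815 over 14414 pairs, above the highest of 1000 shuffles (0.0263), across genes that are not independent replicates. The 9 other splits of the 6 libraries gave 0.0516 to 0.12, so this correlation is not particular to the treatment.

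DESeq2 called 86 genes where edgeR called 0 (1139 at an unadjusted p under 0.05). The 6 libraries can be parted 3 against 3 in 10 ways, too few for a share under 0.05. All 10 gave an edgeR count as large as the real 0, as any count must, so that comparison tells nothing (highest other 0). An unadjusted count as large as 1139 came from 3 of 10 (highest other 2058), and a DESeq2 count as large as 86 from 3 of 10 (highest other 170). The splits above the real one put control 1 and Mn-exposed 13, the pair with ID number 1, on the same side. Only 4 splits part all 3 pairs of ID numbers, and of these the real one had the most. It had 86 DESeq2 calls and 1139 genes against at most 49 and 764, and with the block 276 and 2115 against at most 210 and 982. This ranking decides nothing, since 4 splits are too few and the restriction drops the splits above the real one. The ID numbers were also taken as pairs from correlations in these same data. In simulated sets of the 15252 genes edgeR tested, with no change, DESeq2 called up to 41 genes, and 94 in the real counts of the same genes. The simulated genes were drawn independently and so lack variation shared between genes, and another split of the real counts, over all genes, gave 170 calls. Part of the calls may be false, and these numbers do not settle how many.

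A candidate explanation is that variation of control 1 and Mn-exposed 13 hides differences from edgeR. Leaving both out gave 58 edgeR calls and each of the 8 other choices of 1 control and 1 Mn-exposed library gave 0, although these 2 libraries were picked from the same data. The same removal raised the DESeq2 count from 86 to 892, so the gap between the tools did not close. Only 11 of the 58 were among the 86, so most of the 86 were not called by edgeR there. Neither library left out had a part in choosing the 892 genes. The median position of Mn-exposed 13 in them was 0.178, where 0 is the mean of the controls kept and 1 that of the Mn-exposed libraries kept. Both libraries left out lay near the control end in 415 and near the Mn-exposed end in 114. They parted as labelled in 13 and in reverse in 9. In the 8 other choices these counts ran from 10 and 10 (control 1 and Mn-exposed 17, 186 genes) to 8 and 0 (control 2 and Mn-exposed 14, 19 genes) and 4 and 0 (control 4 and Mn-exposed 17, 5 genes). The 58 were not placed this way, and the 86 were called with both libraries. An effect of Mn in the 58 and the 86 stays open, since no further samples were tested.

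Control 1 and Mn-exposed 13 resemble each other more than either resembles its own group. A swap of their labels is argued against by control 1, which correlates less with Mn-exposed 14 and 17 (mean 0.9564) than with control 2 and 4 (mean 0.9729). Control 1 also lies at the other end of the first component from Mn-exposed 14 and 17. The second component goes the other way for control 1: there control 1 (9.06) lies with Mn-exposed 14 (8.57) and 17 (10.1), apart from control 2 (-18.5) and 4 (-28.9). For Mn-exposed 13 (19.7) that component speaks against a swap, since it lies on the same side, farthest from control 2 and 4. The second component is thus divided, and a swap is not excluded. In the 295 genes called without it, control 1 was nearer the Mn-exposed libraries (0.805, where 0 is the mean of the controls and 1 that of the Mn-exposed libraries). That position decides nothing, since Mn-exposed 13 is in that mean, and without both libraries it was 0.0555 (892 genes, quartiles -0.435 and 0.629). Whether Mn-exposed 13 alone carries a wrong label cannot be told apart from a right one: it correlates better with control 2 and 4 (0.9794 and 0.9746) than with Mn-exposed 14 and 17 (0.9634 and 0.9718) and its position was 0.178 in the 892 genes (quartiles -0.251 and 0.648; 0.0898 in the 751 genes called without it, where control 1 is in the control mean), but it lies with the other Mn-exposed libraries, beyond all controls, in the 4 genes described by ID and in all 86 DESeq2 calls, which were selected with its label. Of the 892 genes, 415 had both libraries near the control end and 114 had both near the Mn-exposed end. Another 13 had Mn-exposed 13 near the Mn-exposed end and control 1 near the control end, and 9 the reverse. The ratio of these was 1.44, with an exact 95% interval of 0.571 to 3.83 that covers counting error only. A bias following the length of the gene on the chromosome is argued against as the whole source: with that trend removed in each library, the correlation of their deviations from the group means went from 0.417 to 0.406. A weaker response of Mn-exposed 13 to Mn, variation shared by Mn-exposed 14 and 17 for another reason, and a shared batch or day for ID number 1 stay open and were not tested.

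The mtDNA share was lower in Mn-exposed libraries by 3.21 points. Whether Mn-exposed 14 alone sets this cannot be told apart from a group difference, because the difference without it, -1.73 points, lies between 1 and 2 SDs of the controls. That SD rests largely on control 1, at 16.59% against 13.95% and 13.9% in control 2 and 4. A library-wide difference that also orders the nuclear genes may account for the lower share (r = -0.891 between the share and the first component of nuclear genes). The 2 libraries at that component's far end are both Mn-exposed, so treatment and this axis partly run together. They are not the same, since Mn-exposed 13 (-22.6) lies at the other end beside control 1 (-24). The shares of these 2 were 13.76% and 16.59%, 1 library each, which does not separate the axis from treatment. The slope of expression on gene length along the chromosome, which can follow RNA or library quality, also moves with the share (r = -0.933, or -0.385 without the 2 farthest libraries). It moves with the component too (r = 0.913, or 0.845), in part because both come from the same expression values. An effect of Mn on mitochondrial transcripts stays among the open explanations.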
